A study of Caenorhabditis elegans with 40 samples.

How the data were processed

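HSF-1 fused to a degron and GFP was immunoprecipitated with an antibody to GFP from young adult animals, per the labels. Animals were fixed in 2% formaldehyde, chromatin was sheared to fragments of 200 to 600 bp, and 0.5 µg of chromatin went into each precipitation. The labels give 8 HSF-1 ChIP groups of 2 libraries, set by the tissue of TIR1, auxin or ethanol, and temperature. Nothing in the labels says whether the libraries of a group came from separate cultures. RNA polymerase II ChIP and input libraries were not analysed here.

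Bowtie2 and MACS2 are named in the submitters' processing notes, without versions or settings. The genome build and filters are not given in the sources used here. Each list row gives a summit with the peak score of the authors, and the region of the depletion comparison with its differential score, both per the file headers. The differential score is headed as the negative log of a p-value with no base stated, and was treated as a score. Per the peak names, the summits came from the soma TIR1 strain. Whether the replicates were pooled for the lists is not stated. What a peak score is relative to is not stated either, so scores were used only within a condition. Every region was of the kind lost on depletion by its name, and each of the 468 and 413 listed summits was found in the file of common summits with the same position and score. The germline list after heat shock held 100 rows, of which 8 were exact repeats and were dropped.

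Summits were assigned to genes with the Ensembl release 115 annotation of WBcel235, through any protein-coding TSS within 1000 bp. As the build of the files is not given, the fit of the coordinates was checked. Summits lay within 300 bp of a TSS of 19 of 88 chaperone genes, and when moved by 5000 bp to either side, of 0 and 1. For soma-class peaks after heat shock on chromosome V, 16 lay within 300 bp of a protein-coding TSS as deposited, and 9 and 7 when moved by 500 bp to the left and right. On chromosome I the counts were 6, 2 and 2. On II they were 5, 7 and 3, on III 4, 4 and 3, on IV 5, 5 and 4, and on X all were 0. By the chaperone check, the counts as deposited and moved by 500 bp to the left and right were 4, 2 and 1 on II. They were 2, 2 and 2 on III, and 0, 1 and 2 on IV. The fit to all protein-coding TSSs was thus resolved only on I and V. Gene assignments on II, III, IV and X, among them those of F44E5.4, hsp-60 and hsp-110, rest on a fit that was checked but not resolved. Of the 19973 protein-coding genes, 19956 had the same name in the gene name table used. Near-identical gene copies, such as those of hsp-16.1, hsp-16.48, F44E5.4 with F44E5.5 and the histones, may share reads, and their peaks are uncertain.

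Class shares, counterparts, X and TSS shares and gene lists were compared with Fisher's exact test, and overlaps with 1000 random placements on the same chromosome (seed 1). Medians of the peak score were compared with 100000 permutations. Benjamini-Hochberg adjustment was applied within each family at 0.05. Confidence intervals of shares are exact binomial 95% intervals. The 95% intervals of the stratified differences are percentiles of 100000 binomial resamples, with each rate drawn slightly towards the middle. The 29 gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Named genes were those of the 5 strongest peaks of each class and condition with a TSS within 1000 bp, up to 4 bound members of each list that passed the test, every bound HSP70, small heat shock protein, HSP90 and HSF-1 regulator gene, and the 5 strongest peaks kept, gained or without a counterpart. The count of chaperone genes by class over 6 lists, the test of their peaks, and the other chaperone genes named with it, were chosen after their values were seen.

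The functions were tested on simulated data. In 50 draws of gene sets over 19973 genes, 150 of 150 planted lists were recovered and 3 of 8550 other tests passed. Genes were drawn singly and the planted lists held more bound members than any called list. The draws thus do not cover list genes that share a peak, or lists with few bound members. Of 400 simulated peaks, the 200 copied from the other condition were found, all with their class. The copies were moved only slightly and the other peaks were placed away from every listed region. This thus checks the code only, not the matching of crowded or shifted peaks. For the exact test of equal odds ratios, 35 of 1000 simulated pairs with the same odds ratio gave p under 0.05. The simulated conditions were independent, while most sites in the data were listed in both. Alternatives changed the overlap, TSS distance, unit counted, background and score threshold. The planned searches for heat shock elements and E2F-like motifs were not run, because no genome sequence was used here. The planned test per library was not run, because the lists hold no values per library. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.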

Results

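HSF-1, the conserved transcription factor of the heat shock response, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in young adult Caenorhabditis elegans whose endogenous HSF-1 carried a degron and GFP. The degron is recognised by TIR1, a plant F-box protein that was expressed either in the soma or in the germline, so that auxin removed HSF-1 from one tissue. Animals spent 2 h on auxin or ethanol (control) plates and were then collected at 20 °C or after 30 min at 34 °C. The labels describe 40 libraries, of which 16 were HSF-1 ChIP libraries in 8 groups of 2, 16 were RNA polymerase II ChIP libraries and 8 were inputs. The values analysed here were 6 lists of HSF-1 peaks and 2 files of peak summits common to the control strains. No list held values per library, so the spread between replicates and the depth of the libraries are unknown, and the tests treat peaks or genes as the units. Peaks and genes are not replicate animals, and the p-values cover only the sampling of peaks or genes. A peak is called soma, germline or shared here when it stands in the authors' list of regions lost on depletion in the soma, in the germline or in both.

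The first question was how HSF-1 sites were divided between the tissues before and after heat shock. At 20 °C the lists held 468 distinct peaks, with 47 in the soma class, 242 in the shared class and 179 in the germline class. After heat shock they held 413, with 64 in the soma class, 257 in the shared class and 92 in the germline class. The germline class made up 38.2% of the listed peaks at 20 °C (exact 95% confidence interval 33.8 to 42.8) and 22.3% after heat shock (18.4 to 26.6), a difference of -15.97 percentage points (Fisher's exact test, two-sided, p = 2.83e-07, Benjamini-Hochberg adjusted over 2 tests 5.67e-07). The soma class made up 10.0% at 20 °C (7.47 to 13.1) and 15.5% after heat shock (12.14 to 19.4), a difference of 5.45 points (Fisher's exact test, p = 0.019, adjusted 0.019). When only peaks at or above the median score of their list were used, the soma difference was no longer called (Fisher's exact test, adjusted p = 0.115). A cut of each list at its own median keeps the class shares by construction, so this alternative cannot test them. The shared class made up 51.7% and 62.2%. With bound genes counted instead of peaks, each gene once and a gene of several classes as shared, the soma difference was 38.6 points (Fisher's exact test, adjusted p = 2.01e-15) and the germline difference -23.7 points (adjusted p = 1.66e-06). By this count the soma class held 30 of 240 genes at 20 °C and 71 of 139 after heat shock, the shared class 110 and 43, and the germline class 100 and 25. This count leaves out peaks with no protein-coding TSS within 1000 bp, and treats genes that share a peak as separate units. After heat shock it drew on 48 of 64 soma-class, 42 of 257 shared-class and 23 of 92 germline-class peaks. Its differences are thus not on the same footing as those of all peaks. The intervals cover counting error only. The tests treat the lists as independent sets, although 340 of the 468 peaks at 20 °C overlapped a peak listed after heat shock. Among listed peaks, the highest number in the name of a germline depletion region was 716 at 20 °C and 346 after heat shock. For soma regions it was 336 and 374. A lower sensitivity of the germline comparison after heat shock was not tested and cannot be told apart from a smaller germline share of sites.

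The next comparison asked whether the sites of unstressed and heat-shocked animals were the same. Of the 468 peaks at 20 °C, 340 (72.6%) overlapped a peak listed after heat shock by at least 1 bp, against a mean of 3.14 and a maximum of 12 in 1000 random placements on the same chromosomes (one-sided permutation test, p = 0.001, the smallest these placements can give). In the other direction 350 of 413 peaks (84.7%) overlapped. Among all common summits, 350 of 500 at 20 °C lay within 100 bp of 1 of the 441 after heat shock (70%, random mean 0.478, one-sided permutation test, p = 0.001). The strongest sites were present in both conditions. They included an intronic site of tir-1, which encodes a Toll and interleukin receptor domain protein, at position 3897311 on chromosome III, and a site in the 5' UTR of pck-2, which encodes a phosphoenolpyruvate carboxykinase, at position 7869253 on chromosome I. The other strongest sites kept were intergenic, at 143424 on chromosome X (nearest TSS that of Y73B3A.8), 15321128 on chromosome V (nhr-247) and 1375251 on chromosome X (fbxa-190), and by the scores after heat shock also at 2058109 on chromosome X (Y102A11A.1), all more than 1000 bp from a protein-coding TSS. Positions are those of the authors' files, whose genome build is not given in the sources used here.

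**Figure D1:**
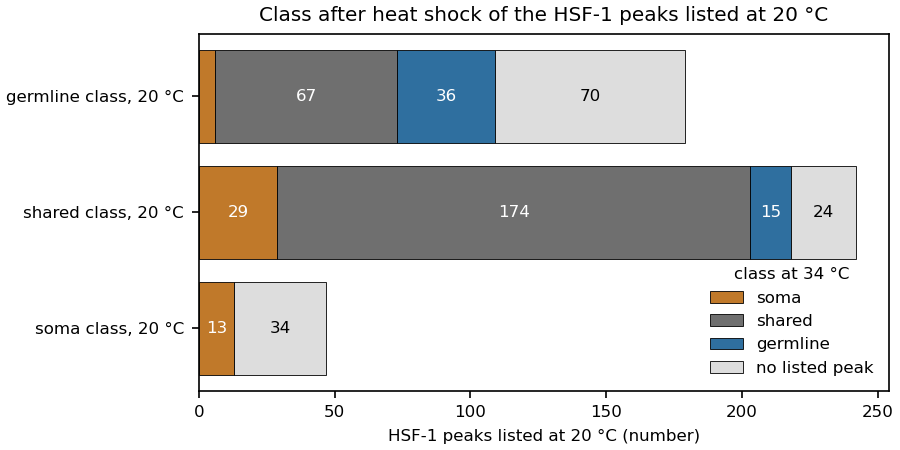
Each bar shows the HSF-1 peaks of 1 class at 20 °C, and its segments give the number that overlapped a peak of each class at 34 °C or no listed peak. Most shared-class peaks stayed shared (174 of 242), while 70 of 179 germline-class and 34 of 47 soma-class peaks had no listed counterpart.

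The classes differed in how often their peaks had a listed counterpart after heat shock. Of the shared-class peaks at 20 °C, 218 of 242 did (90.1%), against 53.98% of the others (adjusted p = 3.85e-18, Fisher's exact test, two-sided, adjusted over 6 tests). Of the germline-class peaks 109 of 179 did (60.9% against 79.9%, exact test, adjusted p = 1.29e-05), and of the soma-class peaks 13 of 47 (27.7% against 77.7%, adjusted p = 1.85e-11). All 13 of these soma-class peaks were again in the soma class, as were 174 of the 218 shared-class peaks in the shared class (79.8%). Only 36 of the 109 germline-class peaks were again in the germline class (33.0% against 81.0% of the others keeping their class, exact test, adjusted p = 3.85e-17), and 67 were in the shared class. When only peaks at or above the median score of their list were used, 34.4% of germline-class and 16.7% of soma-class peaks had a counterpart (Fisher's exact test, adjusted p = 2.06e-12 and 1.23e-06). Each list was cut at its own median, after heat shock 7994 in the shared, 607 in the germline and 283 in the soma class. Counterparts were thus removed at unlike scores, and these shares do not test the class difference. In every class, peaks with a counterpart had a higher median score at 20 °C than those without. The medians were 2302 and 215 in the shared, 322 and 110 in the germline and 330 and 93.7 in the soma class. The classes also differed in peak score and were not compared at equal score, so class and peak strength cannot be told apart here. A missing counterpart does not mean that no summit was called: 14 of the 128 peaks at 20 °C with none had a common summit after heat shock within 100 bp that stood in no class. The strongest peaks without a counterpart lay near the start of chromosome I (position 229), beside rpn-2 (a proteasome subunit gene) and C23G10.7, beside hcp-3 (which encodes the centromeric histone H3), in intronic sequence where csr-1 (an Argonaute gene) and frpr-10 overlap, and in an intron of F58G1.7. All of these but the site on chromosome I had a common summit in no class after heat shock within 100 bp, so a summit was still called there. The strongest peaks found only in the lists after heat shock lay in introns of Y32B12B.2 (nearest TSS that of srbc-65) and scp-1, and in intergenic sequence nearest to rcq-5, nhr-241 and Y53G8AL.1.

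Chaperone promoters were examined for their class in each condition. Of 88 genes in 6 chaperone lists, 29 had a common summit within 1000 bp of a TSS in at least 1 condition. The promoters of 17 of them were in the shared class at 20 °C and in the soma class after heat shock. These included F44E5.4 and F44E5.5, inducible HSP70 genes that share a promoter, hsp-16.2 and hsp-16.41, small heat shock protein genes that share another, both annotated copies of hsp-16.1 and of hsp-16.48, and hsp-90 with its co-chaperone genes sti-1, fkb-6, ahsa-1 and sgt-1. The mitochondrial chaperone gene hsp-60, its neighbour Y22D7AL.10, dnj-12 and cct-8 did the same. These 17 genes lay at 12 peaks. Of all TSS-proximal shared-class peaks at 20 °C, 27 of 76 turned soma, with 12 of 19 at genes of the chaperone lists and 15 of 57 at other genes (Fisher's exact test, two-sided, unadjusted p = 0.00561, chosen after the data were seen). The germline differential score at 20 °C had a median of 57.9 at the 12 peaks, against 117 at all TSS-proximal shared-class peaks and 341 in the whole shared class. It was 61.2 at all 19 peaks of chaperone genes and 147 at the 57 of other genes. At the 15 peaks of other genes that turned soma it was 47.65. The higher share at chaperone genes thus cannot be told apart from their lower germline scores. The constitutive HSP70 gene hsp-1, the HSP110 gene hsp-110 and the J-domain gene dnj-13 were in the shared class in both conditions. The promoters of hsp-4, the endoplasmic reticulum BiP gene, and hsp-70 were listed only after heat shock, in the soma class, although hsp-70 had a common summit in no class at 20 °C. The mitochondrial HSP70 gene hsp-6 was in the soma class in both, the prefoldin gene pfd-1 in the soma class at 20 °C and in no list after heat shock, and cct-5 in the germline class at 20 °C and in the soma class after heat shock. Peaks at cct-3, cct-7, dnj-19 and, 738 bp downstream of its TSS, sip-1 were in the shared class at 20 °C and in no list after heat shock. The promoter of hsb-1, which encodes a negative regulator of HSF-1, was in the shared class at 20 °C and had a summit in no class after heat shock.

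The gene lists were compared with all 19973 protein-coding genes. At 20 °C the shared class bound 110 genes, among them 7 of 16 small heat shock protein genes (adjusted p = 2.42e-10, one-sided Fisher's exact test, adjusted over 174 tests), 5 of 12 HSP90 and co-chaperone genes (adjusted p = 1.24e-07) and 4 of 11 HSP70 genes (adjusted p = 8.09e-06). It also bound 3 of 14 genes of the CCT chaperonin and prefoldin (cct-8, cct-3 and cct-7), 3 of 29 J-domain genes, 2 of 9 mitochondrial chaperone and protease genes and 3 of 25 genes of P granules and small RNA pathways (csr-1, hrde-1 and glh-1), with adjusted p from 0.000985 to 0.0113. The germline class at 20 °C bound 5 of 73 histone genes (his-5, his-6, his-39 and his-67 with his-68, Fisher's exact test, adjusted p = 0.000762) and 4 of 80 ribosomal protein genes (rpl-31, rpl-3, rpl-20 and rps-22, adjusted p = 0.00939). After heat shock the soma class bound 71 genes, among them 6 small heat shock protein genes (Fisher's exact test, adjusted p = 1.1e-09), 5 HSP70 genes (adjusted p = 1.3e-08), 5 HSP90 and co-chaperone genes (adjusted p = 1.66e-08), 3 mitochondrial chaperone and protease genes, 2 of the CCT list (cct-8 and cct-5) and both nucleotide exchange factors listed, unc-23 and bag-1. The shared class after heat shock held hsp-110 and hsp-1, and its germline class held his-5, his-6 and his-39. The soma class at 20 °C passed for 1 list, through the single gene unc-23.

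Several of these genes shared 1 peak, so the counts of genes overstate the number of independent sites. The 6 small heat shock protein genes of the soma class after heat shock lay at 3 peaks, and the 5 histone genes at 20 °C lay at 2. When each peak was given only to its nearest TSS, 6 of the 18 list calls held, those of small heat shock proteins and of HSP90 and its co-chaperones in both classes, and those of HSP70 and of nucleotide exchange factors in the soma class after heat shock. The calls of P granule genes (Fisher's exact test, adjusted p = 0.287) and of the CCT list in both classes were among those lost. With a TSS distance of 500 bp the histone calls in both conditions (Fisher's exact test, adjusted p = 0.189 at 20 °C), the ribosomal protein call (adjusted p = 0.1943) and the mitochondrial chaperone call of the shared class were lost. With peaks at or above the median score of their list, 9 calls were lost. These were both HSP90 calls, with 1 bound gene each (Fisher's exact test, adjusted p = 0.1945 and 0.2279), both CCT calls, the P granule call, the histone and ribosomal protein calls at 20 °C, the shared-class HSP70 call and the soma-class nucleotide exchange factor call after heat shock. The small heat shock protein calls of both classes and the HSP70 call of the soma class after heat shock were lost only with bound genes as background. Against a background of the genes with any listed peak, 0 of 18 held, with adjusted p from 0.107 to 1. In direct tests of the lists between classes and between conditions, 0 of 90 passed Benjamini-Hochberg adjustment of Fisher's exact test, and 3 had an unadjusted p under 0.05. With all genes as background, only the small heat shock protein calls and the soma-class HSP70 call thus held under every alternative. Without near-identical gene copies, the soma-class small heat shock protein call rested on 2 genes (Fisher's exact test, adjusted p = 0.00985). These were hsp-16.2 and hsp-16.41, which share a single summit. The shared-class call at 20 °C then rested on 3 genes. A difference of any single list between classes was not shown.

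**Figure D2:**
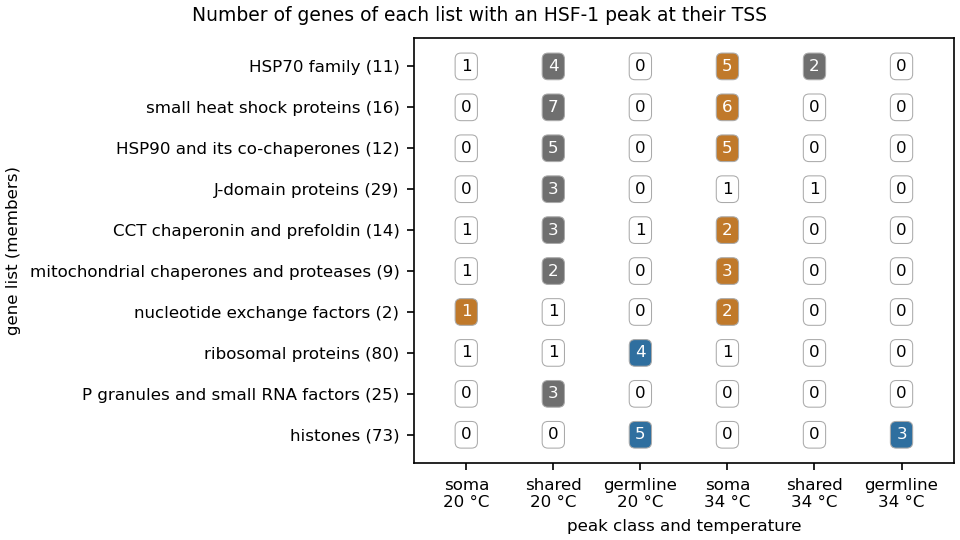
Rows are the gene lists that passed the test in at least 1 class, with their number of members, and columns are the peak classes at each temperature. Each number counts bound genes, and a filled box marks an adjusted p of at most 0.05 against all protein-coding genes. The shared class at 20 °C and the soma class at 34 °C hold 7 and 6 of the 16 small heat shock protein genes.

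Peaks of the classes lay at different distances from genes. After heat shock 48 of 64 soma-class peaks (75%, exact 95% confidence interval 62.6 to 85.0) lay within 1000 bp of a protein-coding TSS, against 42 of 257 shared-class peaks (16.3%, 12.0 to 21.4) and 23 of 92 germline-class peaks (25.0%, 16.6 to 35.1). Random placements gave 42.0 to 43.3% for these classes, so the soma class lay above and the other classes below (two-sided permutation test, adjusted p = 0.003 for each). The soma class differed from the shared class by 58.7 points (adjusted p = 6.22e-18, Fisher's exact test, two-sided, over 9 tests) and from the germline class by 50.0 points (adjusted p = 2.93e-09), or by 28.0 points with a TSS distance of 2000 bp (adjusted p = 0.000998). At 20 °C the shares were 53.2% in the soma class, 31.4% in the shared class and 43.02% in the germline class. Random means were 40.65, 42.2 and 41.5%, and only the shared class differed (two-sided permutation test, adjusted p = 0.139, 0.003 and 0.755). Soma against germline was not called (10.2 points, Fisher's exact test, adjusted p = 0.25). Soma and germline each differed from shared (21.8 and 11.6 points, Fisher's exact test, adjusted p = 0.0125 and 0.0274). From 20 °C to heat shock the share changed by 21.8 points in the soma class (Fisher's exact test, adjusted p = 0.0327), by -15.1 points in the shared class (adjusted p = 0.000268) and by -18.02 points in the germline class (adjusted p = 0.00804). With a TSS distance of 500 bp the soma change was 33.6 points. With 2000 bp the soma change (17.4 points, exact test, adjusted p = 0.0896) and the germline change (-2.6 points, adjusted p = 0.701) no longer passed. None of these 3 changes passed when only peaks at or above the median score of their list were used. The tests of these changes treat the lists as independent sets, although most sites were listed in both conditions.

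**Figure D3:**
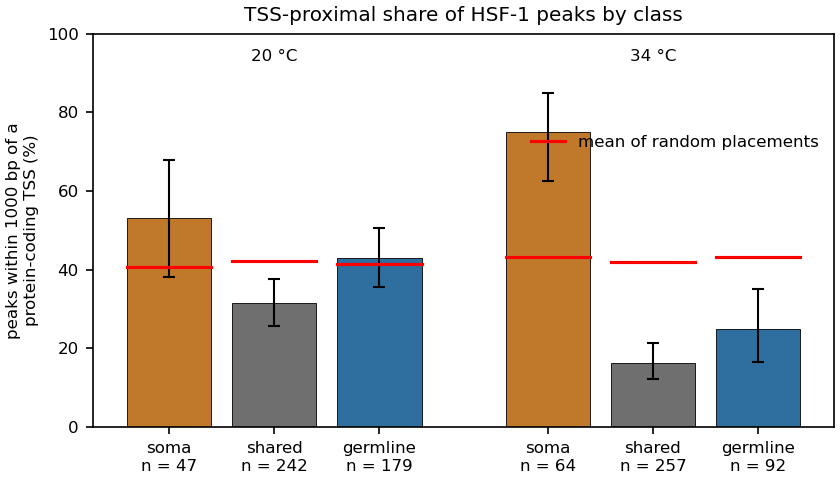
Bars give the percentage of HSF-1 peaks of each class within 1000 bp of a protein-coding TSS, error bars the exact 95% confidence interval, and red lines the mean of 1000 random placements. The soma class at 34 °C stands at 75%, above its random mean, and the shared class at 16.3%, below it.

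The peaks with a TSS within 1000 bp named by their score were as follows. In the soma class at 20 °C they lay beside F19B2.5, unc-23 (a BAG domain co-chaperone gene), Y43F8B.2, hsp-6 and ftt-2 (a 14-3-3 protein gene). In the shared class they lay beside pck-2, col-52, ZK1053.2 (2 summits) and C53C11.4, and after heat shock also beside ZC262.7. In the germline class at 20 °C they lay beside Y54B9A.1, hcp-3, Y53F4B.7, F01G4.4 and klp-7 (a kinesin gene). After heat shock the germline-class set held Y54B9A.1, srw-10, arrd-16, his-39 and fbxa-194. The soma-class set after heat shock held F44E5.4, both hsp-16.1 copies, R107.5 and hsp-16.41. The summit between F44E5.4 and F44E5.5 lay at position 11759473 on chromosome II, in intergenic sequence 162 bp and 189 bp upstream of their TSSs. The summits between hsp-16.1 and hsp-16.48 lay at 9087954 and 9089944 on chromosome V, also intergenic.

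Shared-class peaks were the strongest by the authors' peak score, which has no stated reference and is compared here only within a condition. A peak is in this class only if both depletions called it lost, and no summit in the 2 highest quartiles of the score stood in no class, so the definition of the class itself favours strong peaks. At 20 °C the median score was 2079 in the shared class, 212 in the germline class and 120 in the soma class. The germline class had 0.102 and the soma class 0.058 times the shared median (two-sided permutation test of medians, adjusted p = 3e-05 and 0.00106). After heat shock the medians were 7994, 607 and 283, with ratios of 0.0759 (permutation test, adjusted p = 3e-05) and 0.0354 (adjusted p = 0.00012) to the shared class. By the differential score the soma class was no longer called below the shared class, with 0.788 times its median at 20 °C (permutation test, adjusted p = 0.194) and 0.989 times after heat shock (adjusted p = 0.939), while the germline class had 0.25 times the shared median in each condition. Among TSS-proximal peaks alone its ratio of peak scores was 0.165 at 20 °C and 0.0491 after heat shock, and that of the soma class at 20 °C was 0.125. The soma class was below the germline class in both conditions (permutation test, adjusted p = 0.0333 and 0.0168). Among TSS-proximal peaks alone it was still lower, with 0.759 and 0.843 times the germline median, but the call was lost (permutation test, adjusted p = 0.486 and 0.63).

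**Figure D4:**
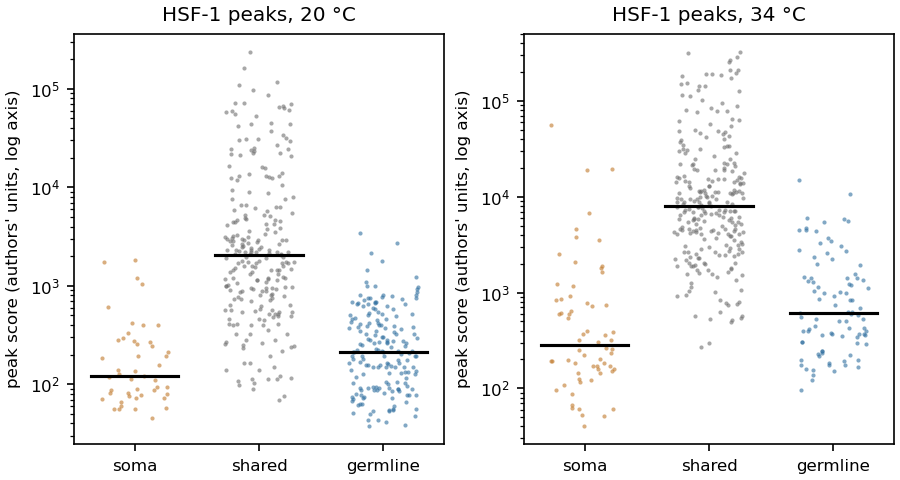
Each point is an HSF-1 peak, with its score in the authors' units on a log axis, by class at 20 °C and at 34 °C, and black lines are medians. The shared class is highest in each panel, with medians of 2079 and 7994, and the panels are not on a common scale of signal.

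The X chromosome, which is largely silent in the germline, was examined as a check of the classes fixed in advance. At 20 °C it held 14.9% of soma-class, 8.68% of shared-class and 7.82% of germline-class peaks, against 13.7% of protein-coding genes. After heat shock it held 4.69%, 11.3% and 8.7%. None of 10 tests passed adjustment (Fisher's exact test, two-sided, lowest adjusted p = 0.116), and 3 had an unadjusted p under 0.05. Neither the soma nor the germline class differed from the shared class (Fisher's exact test, lowest adjusted p = 0.369), and the soma class after heat shock was lowest. The check thus did not separate the classes. Among TSS-proximal peaks alone, X held 1.32% of the shared class (n = 76) and 2.6% of the germline class (n = 77) at 20 °C and 0% of the soma class (n = 48) after heat shock. Each was below the share of genes (Fisher's exact test, adjusted p = 0.00317, 0.00743 and 0.00639). These shares rest on very few peaks on X and on the coordinate fit there, which was not resolved.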

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

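The patterns below were noticed in the lists, and the finer strata, the intervals of the stratified differences, the values without the lowest quartile and the exact tests of equal odds ratios with their alternatives were chosen after the data were seen.

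The classes differed in how their TSS-proximal share changed from the lists at 20 °C to those after heat shock. Of 76 TSS-proximal shared-class peaks, 27 turned soma, so the soma rise and the shared fall partly count the same sites. The tests ignore this pairing, although 340 of 468 peaks at 20 °C overlapped a peak after heat shock. The change of the TSS-proximal share was 36.9 points higher in the soma than in the shared class and 39.8 points higher in the soma than in the germline class (Zelen's exact test of equal odds ratios, adjusted p = 0.000492 and 0.000825). The germline and shared classes differed by -2.95 points (exact test, adjusted p = 1). With a TSS distance of 2000 bp, the soma class differed from the shared class by 34.0 points (exact test, adjusted p = 0.00411), and from the germline class by 20.0 points, no longer past the threshold (adjusted p = 0.082), and germline minus shared turned to 14.0 points. With peaks at or above the median score of their list, soma against shared (31.6 points, exact test, adjusted p = 0.0674) no longer passed and soma against germline (44.0 points, adjusted p = 0.0134) did. The share of peaks at 20 °C with a listed peak after heat shock also differed between classes, at 27.7% in the soma, 90.1% in the shared and 60.9% in the germline class, each tested against the other classes. The classes were not compared at equal peak score.

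The shared-class sites that turned soma after heat shock were mostly promoter sites. Among shared-class peaks with a counterpart, the share that turned soma was 47.9 points higher for TSS-proximal than for distal peaks (n = 218). Weak peaks after heat shock may have escaped the germline call. Within quartiles of the score after heat shock the difference was 32.9 points (95% interval 22.6 to 46.3, permutation p = 1e-05) and 39.3 points with 8 strata. This argues against the peak score after heat shock as the whole cause. That score is from whole control animals of the soma TIR1 strain and does not give the germline part of the signal. A weak germline signal after heat shock thus stays open. The difference of 32.9 points came mostly from the lowest quartile, where 88.0% of proximal and 6.67% of distal peaks turned soma. Without that quartile it was 16.54 points (5 of 30 proximal and 0 of 133 distal peaks, Fisher's exact test, p = 0.000158). Weak germline loss at 20 °C stays open: within quartiles of the germline differential score the difference was 20.8 points (14.7 to 34.3), 19.5 points with 8 strata, and it too came mostly from the lowest quartile, where 81.2% of proximal and 8.7% of distal peaks turned soma, and was 3.31 points without it (Fisher's exact test, p = 0.141). A change in which tissue binds these promoters was not tested, since a higher somatic signal and a lower germline signal cannot be separated in these lists.

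Promoter sites of the germline class mostly had no counterpart after heat shock. Of 77 TSS-proximal germline-class peaks 52 had none (67.5%), against 18 of 102 distal peaks (17.6%). Weaker peaks could have been missed by the peak call after heat shock. Within quartiles of the peak score at 20 °C the kept share of proximal minus distal peaks was still -40.5 points (95% interval -53.0 to -25.23, permutation p = 1e-05), which argues against weak peaks as the whole cause. Loss of germline binding at these promoters remains a hypothesis, and differences in depth or sensitivity between the conditions were not tested.

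The common summit files held 32 summits at 20 °C and 28 after heat shock that stood in no class. Their median scores were 67.0 and 130, below those of every class. They included the hsp-70 promoter at 20 °C and the hsb-1, csr-1 and rpl-20 promoters after heat shock.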

How the results depend on the processing

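By replicate number, no paired analysis was possible because the lists hold no values per library. For the same reason, leaving out replicates was not possible. Sites listed in both conditions form pairs without such values, but no paired test of their class or TSS-proximal share was run. The motif results, their alternatives and the authors' gene annotation were not run. The denominator of all common summits, the counting of clusters once and the leaving out of gene copies were chosen after seeing the data. The depth of the libraries is unknown. Where a result changed, the cause was not tested, except that the stricter lists (peaks at or above the median score of their list) hold fewer peaks. Both overlaps and the germline share kept their direction and side of the threshold under every alternative run. For the germline and soma shares the stricter lists are no test, because a cut of each list at its own median keeps these shares by construction. The share of common summits in listed peaks, which was not tested, stayed at 93.6% at 20 °C and went from 93.65% to 93.88% after heat shock.

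With the stricter lists, these no longer passed: the soma share (5.25 points), the same-class share of soma peaks (100%), and TSS shares of germline against shared at 20 °C (10.7 points) and of heat shock against 20 °C in the soma (28.1), shared (-3.45) and germline (-15.8) classes. Germline against shared after heat shock turned to -1.69 points. With a TSS distance of 2000 bp, soma against shared at 20 °C (12.59 points), germline against shared at 20 °C (4.63) and heat shock against 20 °C in the soma (17.4) and germline (-2.6) classes no longer passed, and germline against shared after heat shock (18.6) newly passed. With clusters counted once, soma against shared at 20 °C (15.1 points) no longer passed. The change of the germline minus that of the shared class turned to 14.0 points with 2000 bp, in a comparison added after seeing the data.

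On X, TSS-proximal peaks alone gave 1.32% (shared, 20 °C), 2.6% (germline, 20 °C) and 0% (soma, heat shock), and genes gave 0.909%, 1.0% and 0%, all newly below protein-coding genes. The soma class at 20 °C turned below genes (12.0% and 10.0%), and the germline class turned above the shared class at 20 °C (2.6% and 1.0%), neither past the threshold. Both alternatives depend on the coordinate fit on X, which was not resolved.

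Of the 18 gene list calls 14 were kept at 500 bp, 18 at 2000 bp, 6 with the nearest TSS only, 9 with the stricter lists (where 10 tests passed) and 0 with bound genes as background. Bound members fell to 0 for histones after heat shock (500 bp), for the CCT list in both conditions (nearest TSS, stricter lists), and, with the stricter lists, for P granule genes and histones at 20 °C and shared-class HSP70 after heat shock. Without gene copies, 16 of the 16 calls with a value held, that of small heat shock proteins in the soma class with 2 genes.

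By the differential score in the authors' deposited table, soma peaks had 0.788 (20 °C) and 0.989 (heat shock) times the shared median. By the peak score, soma had 0.759 and 0.843 times the germline median among TSS-proximal peaks. None of these passed the threshold.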

Other observations

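Shared-class and germline-class HSF-1 peaks lay in the outer parts of chromosomes more often than protein-coding genes did, as measured after the data were seen. These parts make up most of the length of each chromosome. No test was run, and an even spread along the chromosomes was not used as a reference. The parts of each chromosome nearer to an end than the third of its length held 76.4% and 83.7% of shared-class peaks at 20 °C and after heat shock, 82.7% and 87.0% of germline-class peaks, and 59.6% and 67.2% of soma-class peaks, against 62.2% of protein-coding genes. Shared-class peaks were also crowded: 34.3% at 20 °C and 48.6% after heat shock had another listed peak within 2000 bp, against 22.9% and 31.5% of germline-class and 6.38% and 9.38% of soma-class peaks.

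A candidate explanation of strong summits far from any TSS is signal that does not depend on HSF-1, such as a mapping artefact, in a test written after the summits were seen. Of the 194 TSS-distal summits in the highest quartile of scores, 0 stood in no depletion class, which leaves an upper 95% bound of 1.88%. The test decides nothing, because all 41 TSS-proximal summits of that quartile were in a class too, and a depletion call may be reached by any strong summit if library scaling differed. Repeated sequence at these sites was not tested.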
